A study of Homo sapiens with 12 samples.

How the data were processed

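HEK293T cells were transfected by polyethylenimine with plasmids of the PX330-GFP type that carried the 6T or the luciferase sgRNA, with or without Cas9, and polyA RNA was made into libraries with a VAHTS mRNA-seq kit, per the labels' protocols. There were 12 libraries in 4 groups of 3. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples only.

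The authors aligned reads with STAR to hg38, counted them per gene with HTSeq and compared the conditions with DESeq, per the submitters' processing notes, which name no versions. Strand use in the counting is not stated, so genes that overlap on opposite strands are uncertain. The authors deposited 1 table per sgRNA. Its signal values are mean read counts over libraries after division by DESeq size factors, overall and for each of the conditions A and B, per the file headers. The ratio column holds the authors' fold change, the mean of condition B over that of condition A, and the log2 column is its log2, as deposited by the authors. The p-value columns hold the authors' DESeq test and its adjusted value, per the file headers. Both tables are named with Cas9 before no Cas9. The headers do not say which condition held Cas9 or whether the order was the same in both tables. Directions are therefore given as condition B relative to A.

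Reads per library were recovered from the deposited means. Low means are sums of whole multiples of 3 steps, one per library, which give each library's size factor, and for each gene the whole reads that give its mean were searched, within bounds around the mean for abundant genes. A single solution was found for 99.91% and 99.99% of genes above 0 in conditions A and B under the 6T sgRNA and for 99.99% and 99.65% under the Luciferase sgRNA. Genes left out held from 0.73% to 12.09% of the reads of a library, taken at their mean in the library totals. On simulated means the search gave the true reads for 100% of 72769 means, summed over both conditions of both tables. The recovered size factors differed by at most 0.0522% from median-of-ratios factors over all 12 libraries and by up to 36.7% from factors within one table, so the tables share one normalization. Libraries named A1 to A3 and B1 to B3 are in order of size factor and carry no replicate number. Counting error was left to the models across genes, and the interval given for CCL5 covers counting error only.

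Genes past an adjusted p under 0.05 in the authors' deposited DESeq test were the result of each comparison. Beside it, limma (3.58.1, in R 4.3.3) with a mean-variance trend was fitted to the log2 of recovered normalized reads with a pseudocount of 1, for genes with a mean normalized count of 10 or more, with Benjamini-Hochberg adjustment. On counts simulated from the real means, this fit recovered 89% (6T) and 91.9% (Luciferase) of genes changed 2-fold, with 9 and 6 false calls. The simulated spread followed a trend with the mean and held no structure between libraries, and many genes were changed, which loosens the adjusted threshold. The rates therefore do not carry over to the real libraries, where limma did not call IFIT2 under the 6T sgRNA at a log2 fold change of −3.05 (adjusted p = 0.171). The difference between sgRNAs was tested by the difference of the authors' log2 fold changes over a standard error derived from each fold change and its p, two-sided and adjusted over 15273 genes. On simulated values it recovered 200 of 200 changed genes with 13 false calls among 12000 genes. The simulated differences were far larger than those of the real genes with the smallest p. Full recovery there therefore does not show that differences of the real size would be found. Agreement was given as Pearson's r and Spearman's rho across genes, and overlap by Fisher's exact test.

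Before the data were examined, 25 gene lists with 751 genes were fixed, together with the tests, the rule for named genes and most alternatives. Of these lists, 24 had at least 5 measured members and were tested with limma's cameraPR on the signed statistic of the authors' p, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The list of mitochondrially encoded genes had 0 measured members. camera with an estimated correlation and fry were run on the recovered reads, over the 23 lists with at least 5 members there. Medians and counts of members refer to members with a mean normalized count of 10 or more. cameraPR called 1 of 1 simulated lists with a shift and 0 of 20 without.

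Named genes were chosen by a rule. It took, per comparison, up to 12 called genes per direction by largest change with a mean normalized count of 50 or more, the 10 genes with the smallest p where fewer than 10 were called, up to 3 called members or else 2 members by smallest p in each list, and the 10 genes with the smallest p of the difference. Not every gene chosen is named in the text. CDKN1A and IRF9 under the 6T sgRNA, and ISG15, IFI6, TM2D3 and IFIT5, in both tables, were chosen after their values were seen.

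Gene positions, transcript length and GC content came from GENCODE v29 on GRCh38, the assembly also called hg38, by gene symbol. Of the 26485 genes, 24619 (93%) matched. GC content and length were taken from each gene's longest transcript. For the GC correction, a lowess curve with a span of 0.3 of each library's deviation from the mean of the libraries was subtracted. Bootstrap intervals (95%) of a list's median used 10000 draws of its members. They do not measure the spread between libraries. Alternatives tried were other thresholds and filters, centring, other list statistics, voom and library quality weights, GC correction, genes with recovered reads, the order of the conditions reversed in one table, and leaving out each library. Comparisons over both tables at once, with the sgRNA as a term, were chosen after the data were seen. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 was used for the rest. HTSeq's summary categories were left out of all tests, and raw reads were not used here.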

Results

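PolyA RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries the large T antigen of a simian virus, after transfection with plasmids that encoded a single guide RNA (sgRNA) either with or without the Cas9 nuclease. Cells received an sgRNA named 6T or an sgRNA against luciferase, a gene that human cells lack. The 12 libraries formed 4 groups of 3 libraries each, 6T with Cas9, 6T without Cas9, Luciferase with Cas9 and Luciferase without Cas9. For each sgRNA the authors deposited a table that compares the libraries with Cas9 with those without, as mean normalized read counts in a condition A and a condition B. Both tables are named with Cas9 before no Cas9, which does not settle what A and B held. The tables do not state which condition held Cas9, nor whether the order was the same in both. Every difference below is therefore given as condition B relative to condition A. Reads of the single libraries were recovered from these means, and the names A1 to A3 and B1 to B3 carry no replicate number from the labels.

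Reads assigned to genes ranged from 6350972 to 8263902 per library in condition A and from 6659816 to 8293211 in condition B under the 6T sgRNA. Under the Luciferase sgRNA they ranged from 5884892 to 8242529 in condition A and from 19399375 to 38076941 in condition B. Condition and depth therefore went together in the Luciferase table. Each table listed 26485 genes, of which 14051 under the 6T sgRNA and 14087 under the Luciferase sgRNA had a mean normalized count of 10 or more.

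**Figure D1:**
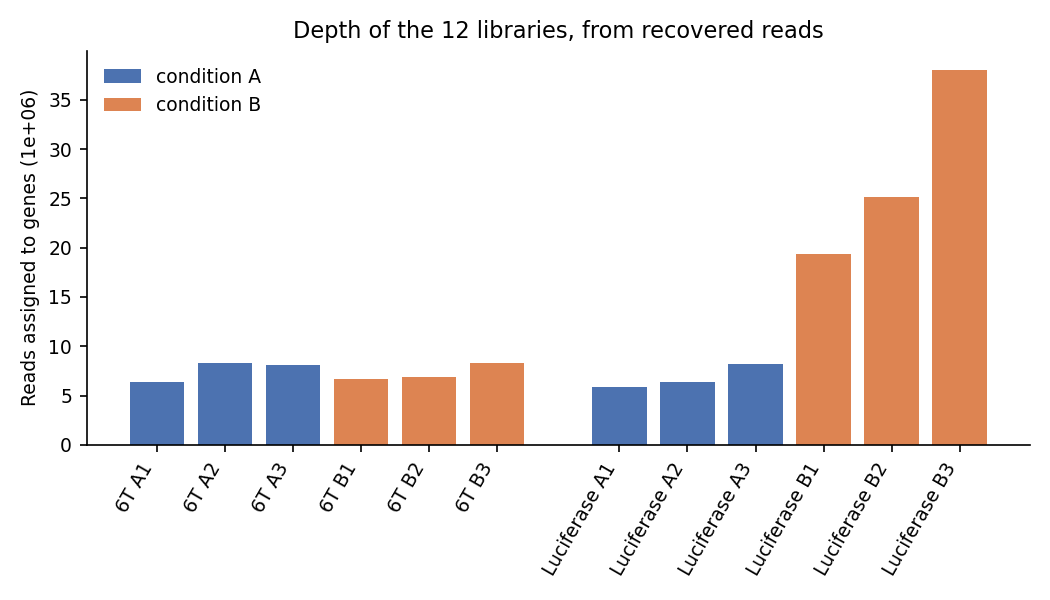
Reads assigned to genes (y axis, in units of 1e+06 reads) in each of the 12 libraries (1 bar per library), coloured by condition. The 3 condition B libraries under the Luciferase sgRNA held 19399375 to 38076941 reads, more than each library of the other groups.

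The comparison under the 6T sgRNA asked which host genes differ in expression between cells with and without Cas9. Antiviral response genes were lower in condition B, and 3 genes of other functions were higher. The authors' deposited test called 8 of 19246 tested genes at an adjusted p under 0.05, with 5 lower and 3 higher in condition B. Among the 11724 genes with a mean normalized count of 50 or more, the median absolute log2 fold change was 0.0899 and 1 gene differed by 2-fold or more.

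All 5 genes lower in condition B belong to the interferon or cytokine response. IFIT2, IFIT3 and IFIT1 encode interferon-induced proteins with tetratricopeptide repeats that restrict viral RNA, OASL encodes a relative of the oligoadenylate synthetases, and CCL5 encodes a chemokine that attracts leukocytes. In the authors' deposited DESeq table IFIT2 was 8.75-fold lower in condition B (log2 fold change −3.13, adjusted p = 4.59e-09). CCL5 was 14.4-fold lower there (log2 fold change −3.85, adjusted p = 0.00554), from 40 recovered reads in condition A against 3 in condition B. The ratio of these summed reads had an exact (Clopper-Pearson) 95% interval, for counting error alone, of 4.14 to 65.7, and with single recovered libraries left out the fold of the means ranged from 9.61 to 26.1. OASL was 4.73-fold lower (log2 fold change −2.24, adjusted p = 0.00734) and IFIT3 4.27-fold lower (log2 fold change −2.09, adjusted p = 0.00629) in the authors' deposited test. IFIT1, the most abundant of them, was 2.13-fold lower in the same test (log2 fold change −1.09, adjusted p = 0.0322).

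In the recovered libraries IFIT2 stood at 60.6 ± 18.8 normalized reads in condition A and 6.92 ± 3.86 in condition B (SD, n = 3). IFIT1 stood at 182 ± 27.5 and 85.2 ± 26.1 normalized reads (SD, n = 3), and OASL at 30.6 ± 2.79 and 6.48 ± 4.34 (SD, n = 3). IFIT3 stood at 39.8 ± 11.1 and 9.32 ± 6.17 (SD, n = 3), and CCL5 at 18.2 ± 6.91 and 1.26 ± 1.20 (SD, n = 3). For each of the 8 called genes, every library of one condition lay beyond every library of the other. Chance alone gives this for 10% of genes, but the 8 were called from these same libraries, so it is no independent support. On the hg38 assembly, IFIT2 (chromosome 10, from 89283694 to 89309276), IFIT3 (chromosome 10, from 89327894 to 89340971) and IFIT1 (chromosome 10, from 89392546 to 89406486) are neighbours in the GENCODE annotation. Members of the IFIT family are similar in sequence, so the split of reads between them is uncertain. OASL lies on chromosome 12 from 121019111 to 121039242 and CCL5 on chromosome 17 from 35871491 to 35880793.

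The 3 genes higher in condition B were PPP1R14B, which encodes an inhibitor of protein phosphatase 1, HMX1, a homeobox transcription factor, and CHCHD10, a protein of the mitochondrial intermembrane space. The authors' deposited DESeq test gave PPP1R14B 1.68-fold higher (log2 fold change 0.75, adjusted p = 0.00666), HMX1 1.70-fold higher (0.76, adjusted p = 0.0132) and CHCHD10 1.57-fold higher (0.65, adjusted p = 0.0322). Recovered libraries gave 815 ± 64.6 and 1369 ± 118 normalized reads for PPP1R14B (SD, n = 3), and 1172 ± 76.2 and 1838 ± 67.6 for CHCHD10 (SD, n = 3). HMX1 had 357 ± 5.06 in condition A and 605 ± 59.8 in condition B (SD, n = 3). PPP1R14B lies on chromosome 11 from 64244480 to 64246941, HMX1 on chromosome 4 from 8846076 to 8871817 and CHCHD10 on chromosome 22 from 23765834 to 23768443. Transcripts of these 3 genes are rich in G and C (68.0%, 73.4% and 68.4%), and log2 fold changes in this table were higher at higher GC content across genes (Spearman's rho 0.36). The next genes by p did not pass: TAF10, a subunit of transcription factor TFIID, had a log2 fold change of 0.63 (adjusted p = 0.138) and HES4, a transcriptional repressor, one of 0.54 (adjusted p = 0.361) in the authors' deposited test.

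The count of called genes depended on the test. limma, fitted to the recovered reads, called 0 of 14035 genes under the 6T sgRNA, with 330 at an unadjusted p under 0.05, against 167 at that level in the authors' test. With single libraries left out, limma's count at that level was lowest at 162, without B3, and highest at 824, without B1. The smallest adjusted p in limma was 0.171, for IFIT2, PPP1R14B and CHCHD10, and CCL5 was below its minimum mean normalized count of 10.

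**Figure D2:**
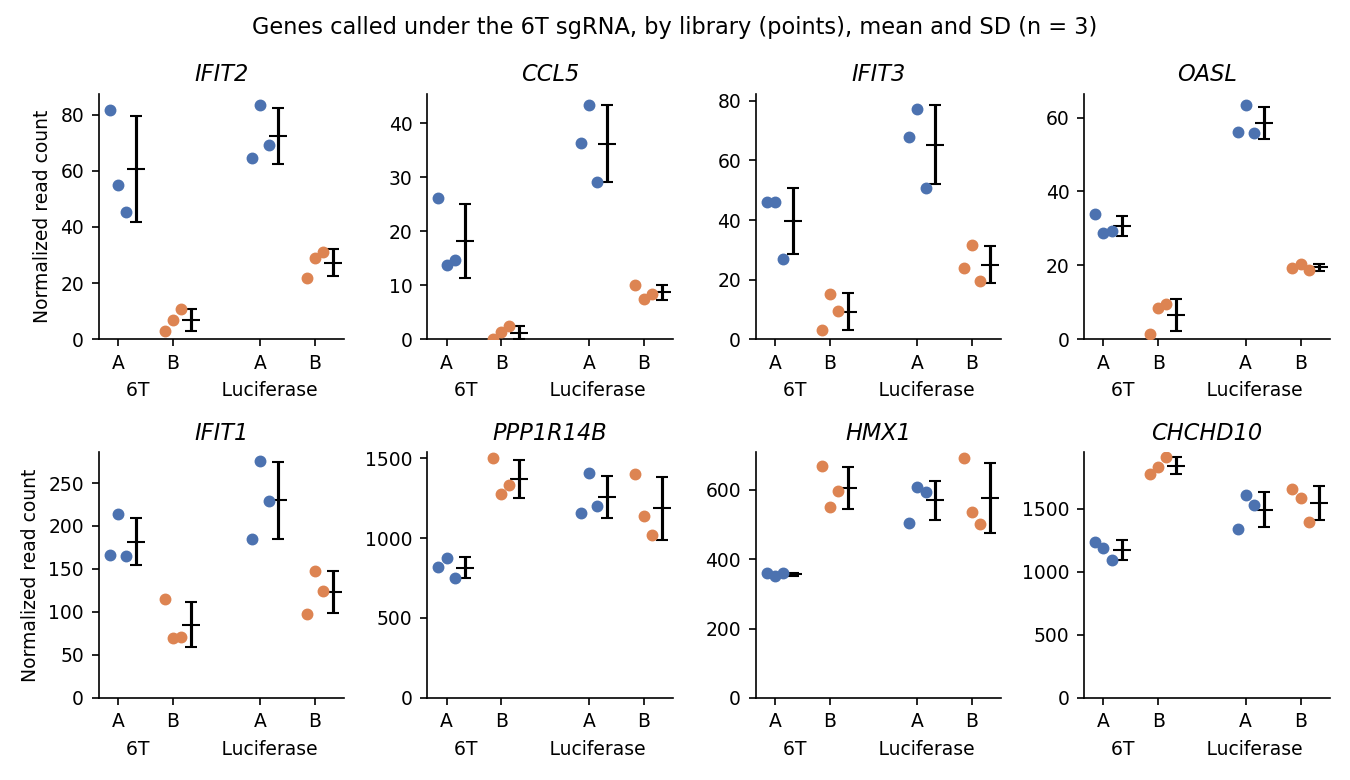
Normalized read count of the 8 genes called under the 6T sgRNA in each recovered library (points, blue for condition A and orange for condition B), with the mean and SD of each group (n = 3), under the 6T and the Luciferase sgRNA. IFIT2 stood at 60.6 in condition A and 6.92 in condition B under the 6T sgRNA, and at 72.3 and 27.3 under the Luciferase sgRNA.

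Under the Luciferase sgRNA the same question was asked with a guide that has no target in human cells. No gene passed an adjusted p under 0.05. The same 5 antiviral genes nevertheless stood at the top by p, with ranks 1, 2, 3, 4 and 7, and each had a lower mean in condition B. In the authors' deposited DESeq table CCL5 was 4.18-fold lower in condition B (log2 fold change −2.06, adjusted p = 0.164) and OASL 3.01-fold lower (−1.59, adjusted p = 0.164). IFIT2 was 2.65-fold lower there (−1.41, adjusted p = 0.854) and IFIT3 2.61-fold lower (−1.39, adjusted p = 1). IFIT1 was 1.86-fold lower in that test (−0.90, adjusted p = 1).

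Recovered libraries under the Luciferase sgRNA gave CCL5 at 36.2 ± 7.10 normalized reads in condition A and 8.68 ± 1.37 in condition B (SD, n = 3), and OASL at 58.4 ± 4.30 and 19.4 ± 0.861 (SD, n = 3). IFIT2 stood at 72.3 ± 9.94 and 27.3 ± 4.81, IFIT3 at 65.3 ± 13.4 and 25.0 ± 6.23, and IFIT1 at 230 ± 45.1 and 123 ± 24.7 (SD, n = 3). IRF9, the DNA-binding part of the interferon-activated factor ISGF3, stood at 133 ± 13.5 and 78.1 ± 6.08 (SD, n = 3). The other genes among the 10 smallest p were DNAH17, a dynein heavy chain, RWDD2A, CENPK, a kinetochore component, and SCARA5, a ferritin receptor. Their log2 fold changes were −1.05, 0.98, 0.77 and −1.19, each with an adjusted p of 1 in the authors' deposited test. PPP1R14B, HMX1 and CHCHD10, the 3 genes higher under the 6T sgRNA, had log2 fold changes of −0.08, 0.02 and 0.05 here.

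Of 20194 genes tested under the Luciferase sgRNA, 246 (1.22%) had an unadjusted p under 0.05 in the authors' deposited DESeq test. Under the 6T sgRNA the share was 0.868%. Both shares lay below what chance alone would give, with median p of 0.637 and 0.676 in that test. The authors' p thus ran large, and a lack of calls does not show a lack of change. limma on the recovered reads also called 0 genes, with 1345 of 14018 at an unadjusted p under 0.05. That count was 287 without library B3, 289 without B2, 805 without A1, 2232 without A2 and 2344 without B1. Among the 11692 genes with a mean normalized count of 50 or more, 13 differed by 2-fold or more and the median absolute log2 fold change was 0.147.

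Among 24 gene lists that were fixed before the data were examined, interferon-stimulated genes were lower in condition B under both sgRNAs. Under the 6T sgRNA, 21 of its 25 members with a mean normalized count of 10 or more were lower in condition B, with a median log2 fold change of −0.29 (camera adjusted p = 3.31e-13). IFIT1, IFIT2, IFIT3 and OASL passed over all genes tested, and the same number, 4, passed adjusted over the list alone. Under the Luciferase sgRNA 21 of 25 members were again lower, with a median of −0.29 (camera adjusted p = 2.71e-12), and 0 members passed over all genes but 6 adjusted over the list alone. These 6 were the 4 genes above with IFI6 and IRF9. With a correlation between genes estimated from the recovered libraries, neither call held (adjusted p = 0.182 under the 6T sgRNA and 0.117 under the Luciferase sgRNA). fry, which asks whether the genes of a list move one way on balance, gave an adjusted p of 0.164 and 0.00707.

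Further members of the list are given as values, and, but for IRF9 under the Luciferase sgRNA, they were chosen after their values were seen. ISG15, a ubiquitin-like modifier, had a log2 fold change of −0.34 under the 6T sgRNA and −1.27 under the Luciferase sgRNA in the authors' tables. IFI6 had values of −0.28 and −0.89, and IRF9 of −0.49 and −0.77. The list of cytosolic nucleic acid sensors and cytokines was also lower in both tables (camera adjusted p = 0.0281 and 0.0459). CCL5 was its single member adjusted over the list alone in each table, and the list's median was −0.03 under the 6T sgRNA and −0.11 under the Luciferase sgRNA. Both calls were lost on the recovered reads with the preset correlation (adjusted p = 0.785 and 0.0800), and with an estimated correlation its adjusted p was 0.899 and 0.603. Under the 6T sgRNA that test held 8 of the 21 members tested, without CCL5. On these 8 the authors' values already gave an adjusted p of 0.823 in camera. On the 9 members held under the Luciferase sgRNA the authors' values kept the call (0.0272).

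Passing in both tables with opposite directions were 3 lists, DNA double-strand break repair, mitosis and cytosolic ribosomal proteins. DNA double-strand break repair genes had a median log2 fold change of −0.06 under the 6T sgRNA, with 29 of 39 members lower (camera adjusted p = 0.0281), and 0.26 under the Luciferase sgRNA, with 33 of 39 higher (1.64e-07). With camera limited to genes with a mean normalized count of 10 or more, the 6T call was lost (adjusted p = 0.0692). Mitosis genes had a median of −0.07, with 35 of 38 lower (camera adjusted p = 0.00732), and 0.23, with 30 of 38 higher (4.68e-05). Cytosolic ribosomal proteins had a median of 0.07, with 63 of 76 higher (camera adjusted p = 2.95e-06), and −0.11, with 57 of 77 lower (0.00377). With an estimated correlation these 3 lists had an adjusted p of 0.898 each under the 6T sgRNA and of 0.603, 0.603 and 0.756 under the Luciferase sgRNA. On the recovered reads with the preset correlation each lost 1 of its calls, repair (adjusted p = 0.104) and mitosis (0.0688) under the 6T sgRNA and ribosomal proteins (0.0679) under the Luciferase sgRNA. Reads were recovered for 70 of 76 ribosomal protein genes under the 6T and 53 of 77 under the Luciferase sgRNA. On these 53 the authors' values had a median of −0.07 and an adjusted p of 0.193 in camera, so the call was already lost on these members. After the correction for GC content in the recovered libraries their medians were −0.03, −0.03 and 0.11 under the 6T sgRNA and 0.13, 0.12 and −0.06 under the Luciferase sgRNA. Many ribosomal protein genes have processed pseudogenes, so their counts are uncertain. No member of these 3 lists passed in either table, over all genes or adjusted over the list alone. The members with the smallest p were TP53BP1 (log2 fold change −0.22) and ATM (−0.28) under the 6T sgRNA and BLM (0.56) and ATM (0.57) under the Luciferase sgRNA. For mitosis they were MKI67 (−0.22) and KIF20A (−0.17), and HMMR (0.54) and ECT2 (0.56). The 6 libraries of a table split 3 against 3 in 10 ways, a comparison chosen after the data were seen. Its measure was the difference in the mean of a list's members per library. Under the 6T sgRNA 7 (repair), 5 (mitosis) and 1 (ribosomal proteins) of the 10 splits reached the real difference, the real split included. The Luciferase counts were 2, 2 and 10.

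Further lists passed in 1 table. Under the 6T sgRNA genes of hypoxia and glycolysis had a median log2 fold change of −0.14, with 27 of 29 members lower (camera adjusted p = 4.42e-07), among them PDK1 (−0.32) and BNIP3L (−0.33). Targets of ATF4, the transcription factor of the amino acid response, had a median of 0.18, with 19 of 22 members higher (9.22e-06). CEBPB had the smallest p of these, at 511 ± 212 normalized reads in the recovered condition A libraries and 940 ± 425 in condition B (SD, n = 3). Cholesterol biosynthesis genes had a median of −0.09 with 21 of 24 members lower (camera adjusted p = 0.0086), with INSIG1 at −0.38. Spliceosome components had a median of −0.07 with 26 of 35 lower (0.0228, and 0.166 on the recovered reads with the preset correlation). Each of these 4 lists had an adjusted p of 0.898 with an estimated correlation. In the splits described above, 3 (hypoxia), 8 (ATF4 targets), 4 (cholesterol) and 5 (spliceosome) of 10 reached the real difference. For ATF4 targets the mean of the members was 9.60 in library B1, below each condition A library. Under the Luciferase sgRNA heat shock response genes had a median of 0.36, with 19 of 22 higher (camera adjusted p = 0.00377), among them HSPA4L (0.80) and DNAJB4 (0.79). Immediate early genes had a median of −0.15, with 21 of 28 lower (0.00256), among them FOSL1 (−0.56) and CYR61 (−0.31). Both lists had an adjusted p of 0.603 with an estimated correlation. Of the 10 splits, 1 (heat shock) and 2 (immediate early genes) reached the real difference.

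In all, 9 lists passed under the 6T sgRNA (7 lower, 2 higher in condition B) and 7 under the Luciferase sgRNA (4 lower, 3 higher). None of these calls held with an estimated correlation, where their adjusted p ranged from 0.182 to 0.899 and from 0.117 to 0.756. The 15 lists that did not pass under the 6T sgRNA had adjusted p from 0.0631 (ribosome biogenesis) to 0.828 (p53 target genes). Next to these stood replication-dependent histones (0.0928), immediate early genes (0.12), proteasome subunits (0.222), blood and immune cell markers (0.263), heat shock response (0.346) and unfolded protein response (0.431). S phase replication, oxidative phosphorylation, apoptosis, NRF2 targets and the extracellular matrix, epithelial and neuronal marker lists each had an adjusted p of 0.749. Of the p53 targets, CDKN1A, a cell cycle inhibitor, stood at 1096 ± 126 and 1058 ± 264 recovered normalized reads under the 6T sgRNA, a gene chosen there after its value was seen, and at 1991 ± 444 and 1217 ± 149 under the Luciferase sgRNA (SD, n = 3).

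Under the Luciferase sgRNA, 17 lists did not pass, with camera adjusted p from 0.0734 (ATF4 targets) to 0.945 (spliceosome components). Cholesterol biosynthesis had 0.101, neuronal markers 0.277, unfolded protein response 0.305 and p53 target genes 0.37. Apoptosis, histones and epithelial markers each had 0.359, extracellular matrix markers 0.544, and hypoxia and immune cell markers 0.606 each. The rest were S phase replication (0.631), NRF2 targets (0.632), oxidative phosphorylation (0.693), ribosome biogenesis (0.79) and proteasome subunits (0.868). The median and the test differed in sign for 5 lists under the 6T sgRNA (p53 targets, histones, oxidative phosphorylation, apoptosis and extracellular matrix markers) and for 2 under the Luciferase sgRNA (S phase replication and proteasome subunits), none of which passed.

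**Figure D3:**
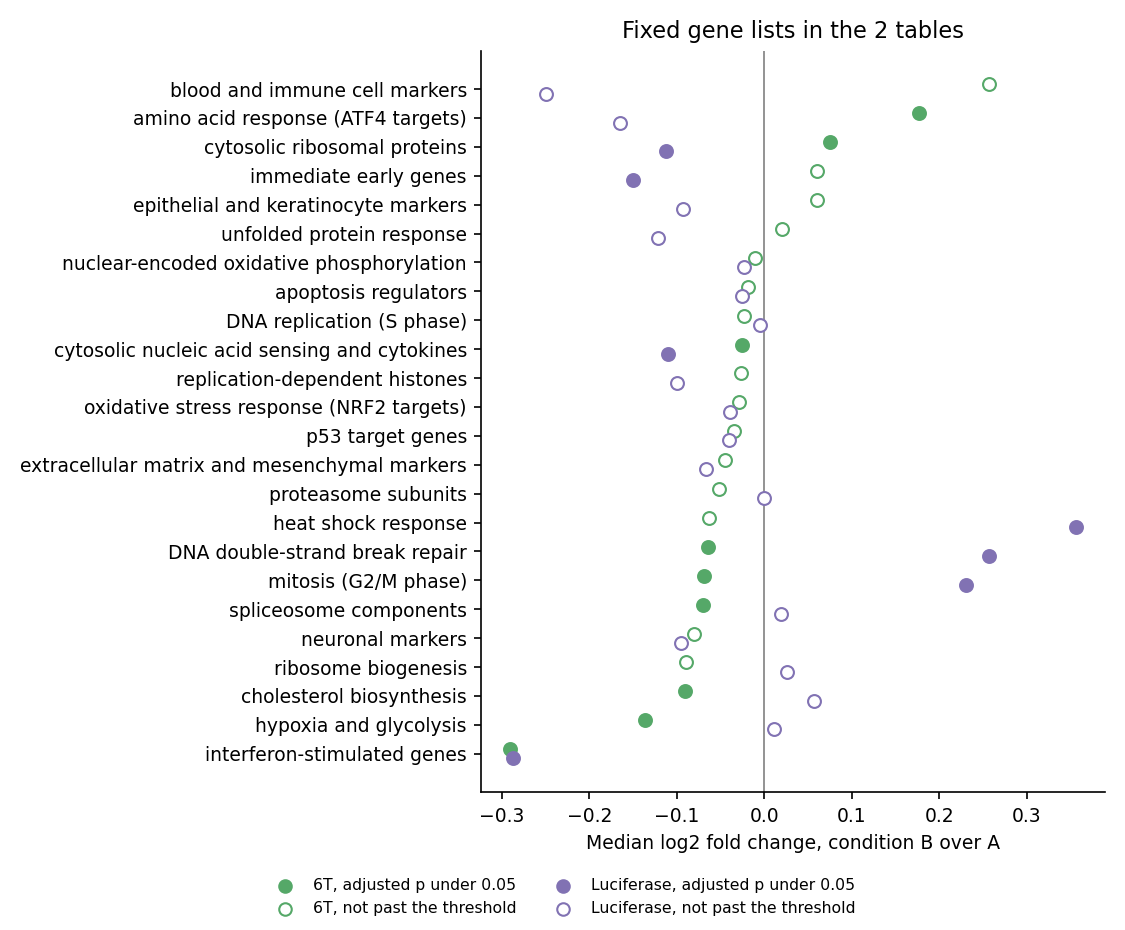
Median log2 fold change (condition B over A) of the members with a mean normalized count of 10 or more of each of 24 gene lists, under the 6T (green) and the Luciferase sgRNA (purple), from the authors' tables. Filled points passed camera with the preset correlation, and interferon-stimulated genes lay at −0.29 under both sgRNAs.

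The difference between the sgRNAs asked whether the contrast of the conditions depended on the guide, as labelled by the tables' own order. In all, 0 of 15273 genes passed a test of the difference of the authors' log2 fold changes, with 324 at an unadjusted p under 0.05. That is fewer than chance alone would give, as the standard errors were derived from the authors' p, which ran large. The lack of calls therefore does not show that the contrast was the same under both guides. PPP1R14B and TAF10 had the smallest adjusted p, 0.868. PPP1R14B differed by −0.83 (SE 0.215) on the log2 scale, Luciferase minus 6T, and TAF10 by −0.64 (SE 0.166). OMA1, a mitochondrial protease, differed by 1.01, GPR27, an orphan receptor, by −0.96 and INSIG2, a regulator of sterol synthesis, by 1.12. The limma interaction on the recovered reads called 0 of 14009 genes, with 1317 at an unadjusted p under 0.05. These counts rest on the order of the conditions. With the order reversed in one table, a setting chosen after the data were seen, the test of the authors' values called 5 genes. These were IFIT2, CCL5, OASL, IFIT3 and IFIT1 (adjusted p from 1.23e-11 to 6.70e-04), with 93 genes at an unadjusted p under 0.05. The limma interaction was not refitted in that order. A limma fit over both tables without an interaction, given below, estimates the same contrast and called 1 gene.

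Of the fixed lists, 8 differed between the sgRNAs by camera with the preset correlation and 16 did not, with adjusted p from 0.107 to 0.942. Interferon-stimulated genes were among the latter (adjusted p = 0.732), so no difference between the guides was shown for them in the tables' own order. Of the 5 lists called in both tables, 2 went in one direction in that order, interferon-stimulated genes and nucleic acid sensing, and 3 in opposite directions. With the order reversed in one table these directions turn round, and 4 lists differed between the sgRNAs. These were interferon-stimulated genes (camera adjusted p = 1.79e-34), nucleic acid sensing (6.22e-04), hypoxia and glycolysis (0.00225) and DNA double-strand break repair (0.0270). With a correlation estimated from the recovered libraries, no list differed between the sgRNAs in the tables' own order (smallest adjusted p = 0.772 in camera of the interaction). No interaction was fitted in the reversed order. The fit over both tables without an interaction, which estimates the reversed contrast, passed interferon-stimulated genes alone (camera adjusted p = 2.31e-04). It is the same result as given below for both tables.

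Across the 13917 genes with a mean normalized count of 10 or more in both tables, log2 fold changes ran in opposite directions more often than in the same one, while the antiviral genes lay together at the low end of both. Pearson's r across genes was −0.25 and Spearman's rho −0.35, and 35.6% of genes had the same sign. With the order of the conditions reversed in one table these values turn to 0.25, 0.35 and 64.4%, and the antiviral genes lie at opposite ends. Genes are not independent replicates, so no p is given. Fold changes followed GC content in opposite directions under the 2 sgRNAs, with Spearman's rho across genes of 0.36 under the 6T sgRNA and −0.69 under the Luciferase sgRNA. After a correction for GC content within each recovered library, r was −0.0272 and rho −0.0757, against −0.20 and −0.31 on the same genes without it. No called gene was shared, since none was called under the Luciferase sgRNA, so the test of overlap could show none (Fisher's exact test, two-sided, p = 1 in each direction). Of the 10 genes with the smallest p in each table, 5 were shared, CCL5, IFIT1, IFIT2, IFIT3 and OASL, where 0.0053 were expected by chance among 18876 genes (exact hypergeometric test, which takes genes as independent, p = 3.18e-15, a comparison chosen after the values were seen).

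**Figure D4:**
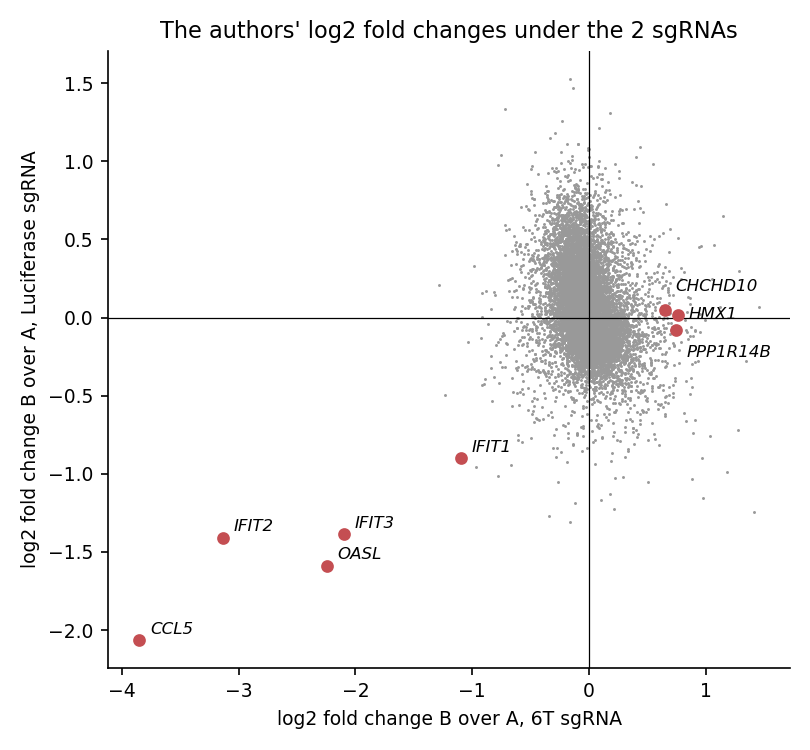
Log2 fold change (condition B over A) in the authors' tables under the 6T sgRNA (x axis) and the Luciferase sgRNA (y axis) for genes with a mean normalized count of 10 or more in both (grey) and the 8 genes called under the 6T sgRNA (red). CCL5 lay at −3.85 and −2.06, and IFIT2 at −3.13 and −1.41.

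Joining the tables asked which genes stood apart in condition B under both guides. This comparison was chosen after the data were seen, and holds only if condition A was the same treatment in both tables. limma on the recovered reads of the 12 libraries, with the sgRNA as a term, called CCL5 alone among 14009 genes, with a log2 fold change of −2.57 (SE 0.334, adjusted p = 0.0277) and 377 genes at an unadjusted p under 0.05 (205 without Luciferase B2, 239 without Luciferase B3 and 1138 without 6T A2). IFIT2 had a log2 fold change of −2.21 (adjusted p = 0.0515), OASL of −1.93 (0.0545) and IFIT3 of −1.76 (0.143) in the same fit, and IFIT1 had an adjusted p of 0.0545. With the GC correction limma called 5 genes, CCL5, IFIT2, IFIT1, OASL and TM2D3, each lower in condition B. Leaving out single libraries gave from 0 to 5 calls, with 5 without 6T B1, 3 without Luciferase A1, 1 without Luciferase A3 and 0 without any of the others.

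Interferon-stimulated genes passed as a list over both tables with an estimated correlation, with a median log2 fold change of −0.29 (camera adjusted p = 2.31e-04 over 23 lists). Their call held without each library in turn (adjusted p from 3.11e-04 to 0.00226) and with the GC correction (3.70e-04). With the order of the conditions reversed in one table, it did not hold (adjusted p = 0.881). A score of the list, the mean of its members per library, was compared over all splits of each table by an exact two-sided permutation test, which gave p = 0.1 under each sgRNA, the smallest that 3 libraries against 3 allow. Over both tables the absolute differences were summed, whatever their direction, so this test does not show a shared direction. Its exact permutation p was 0.01, the smallest that its 100 splits allow. Adjusted over the lists it was 0.23, the value that any list alone at this floor would get.

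**Figure D5:**
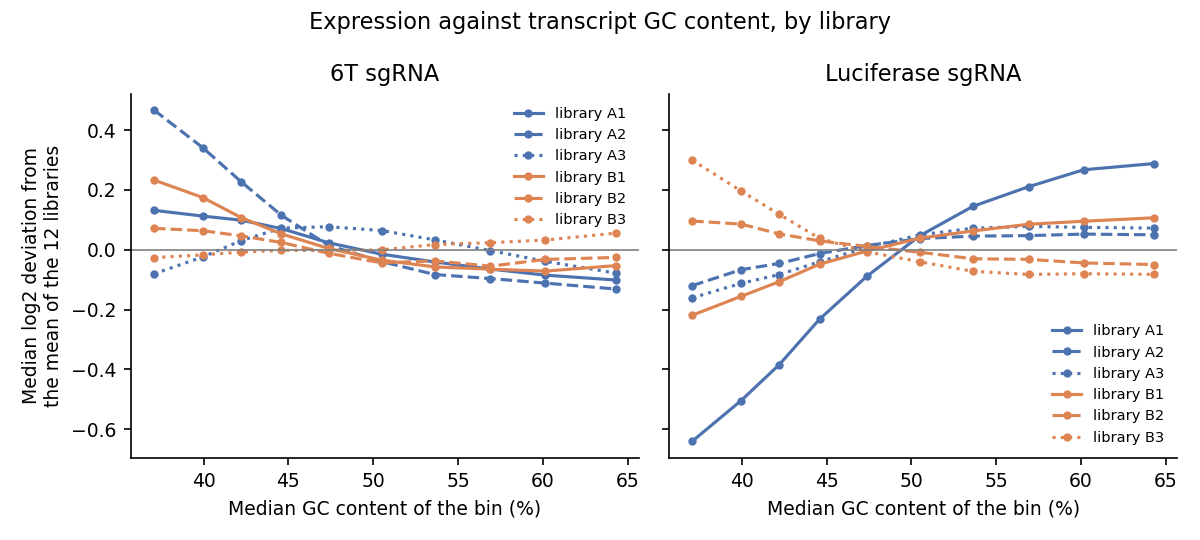
Median log2 deviation of each recovered library from the mean of the 12 libraries, for 10 bins of genes by transcript GC content (x axis, median GC content of the bin in percent), with 1 line per library. Luciferase A1 lay at −0.64 in the bin of lowest GC content, below each other library.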

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

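Apart from the test of transcript length, the tests weighed here were chosen after the results they bear on had been seen, and so were the comparisons of lists with an estimated correlation between the sgRNAs.

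Interferon-stimulated genes had a median log2 fold change of −0.29 in condition B under each sgRNA. CCL5, OASL, IFIT1, IFIT2 and IFIT3 were among the 10 genes with the smallest p in each table. The tables argue against the number of reads as the whole cause: in the 6T table the median depth of condition B was 0.853 of that of condition A, and in the Luciferase table the list's median was −0.26 (95% bootstrap interval −0.78 to −0.08) after condition B was thinned to the depth of condition A. They also argue against the GC trend, with medians of −0.24 (−0.48 to −0.10) and −0.43 (−0.65 to −0.09) under the 6T and the Luciferase sgRNA after its correction, and against a single library, since the weakest median with one left out was −0.21, without 6T B2. Reads shared between IFIT paralogs are argued against for the other 21 members, whose medians in limma were −0.27 (−0.39 to −0.12) and −0.26 (−0.54 to −0.10), but not for the IFIT family, whose summed reads, with those of IFIT5 (log2 fold changes of 0.01 and 0.46 in the authors' tables), had log2 fold changes of −0.60 (SE 0.210) and −0.46 (SE 0.233), the latter within 2 SE of 0. The bootstrap intervals draw the list's members, not libraries, so they leave out the spread between libraries. Thinning keeps any bias already present in the reads, so it cannot speak to how the deeper libraries were made. The split of reads between the IFIT genes stays open. So does a response to Cas9. Each table compares cells with and without Cas9, so the tests of A against B bear on it. The conditions are unnamed, so its direction is not known. A difference between the plasmids or their preparations stays open too. One between library preparations does as well, as condition and depth went together in the Luciferase table. Chance is not excluded either. The list's exact permutation p over both tables was 0.01, the smallest that its 100 splits allow. A list alone at that floor gets 0.23 when adjusted over the lists, so this test could not exclude chance.

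PPP1R14B, HMX1 and CHCHD10 were called higher in condition B under the 6T sgRNA alone, and the test of the difference between the sgRNAs did not pass for any of them. The transcripts of HMX1 and CHCHD10 are at the 99.9 and 99.1 percentile of GC content, and after the GC correction the log2 fold changes of the 3 genes in limma were 0.61 (SE 0.104), 0.55 (0.108) and 0.51 (0.0787), against 0.75, 0.76 and 0.65 before, which argues against the trend as the whole cause. The smallest value was 0.59 after removal of a trend with transcript length and 0.60 with single libraries left out, which argues against each of these. A GC effect that is steeper for these genes than the fitted curve, and a response to the 6T sgRNA with Cas9, stay open.

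Log2 fold changes followed GC content in both tables, with opposite signs. Libraries of one condition differed in the same way: the median deviation of genes of lowest GC content spanned 0.519 within condition B under the Luciferase sgRNA and 0.547 within condition A under the 6T sgRNA, against differences of 0.366 and 0.080 between the condition means. Variation between library preparations is a candidate explanation. The number of reads alone was argued against, since Spearman's rho with GC content was −0.66 after thinning. Thinning keeps any GC difference already present in the reads, so it cannot speak to how the deeper libraries were made. No biological explanation was tested.

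The lists below were singled out because their difference between the sgRNAs, in the tables' own order of the conditions, passed camera with the preset correlation, and with an estimated correlation none of them passed (adjusted p of 0.772 or more). DNA double-strand break repair genes (median log2 fold change −0.06 under the 6T and 0.26 under the Luciferase sgRNA) had an adjusted p of 3.94e-06 in camera. Cytosolic ribosomal proteins (0.07 and −0.11) had 3.94e-06. Mitosis genes (−0.07 and 0.23) had 1.98e-05. ATF4 targets (0.18 and −0.16) had 1.27e-04. Genes of hypoxia and glycolysis (−0.14 and 0.01) had 0.00128. Immediate early genes (0.06 and −0.15) had 0.00291. Cholesterol biosynthesis (−0.09 and 0.06) had 0.00708, and heat shock response (−0.06 and 0.36) had 0.0147.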

How the results depend on the processing

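Tests with limma, recovered reads with a preset correlation, genes with recovered reads, library weights, GC correction, reversed order or both tables were chosen after seeing the data, and the others were planned. Of the 8 genes called under the 6T sgRNA, 5 passed at an adjusted p under 0.01 and 5 had an absolute log2 fold change of 1 or more. Adjustment over genes with a mean normalized count of 10 or more gave 7, since CCL5 has a lower mean, and limma on recovered reads gave 0. Under the Luciferase sgRNA the authors' test gave 0 at each adjusted threshold and filter tried, and so did limma on recovered reads without weights. limma's own 0 calls in each table stayed 0 with pseudocounts of 0.1 and 10, no filter, voom, GC correction and without each library, but library quality weights gave 6 under the 6T and 3111 under the Luciferase sgRNA, where the weights did not converge. The cause was not tested.

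The 9 lists called under the 6T sgRNA became 4 with a correlation of 0.05, 2 with the log2 fold change as the statistic, 6 in the authors' values of genes with recovered reads, 5 on recovered reads, 5 with GC correction, 0 with an estimated correlation and 0 in fry. The 7 under the Luciferase sgRNA became 3 with a correlation of 0.05, 6 in the authors' values of genes with recovered reads, 6 on recovered reads, 9 with GC correction (4 gained, 2 lost), 0 with an estimated correlation and 1 in fry. With the log2 fold change as the statistic, 1 Luciferase call was gained and 2 were lost. Ranks gave 1 call gained and 1 lost in each table. A minimum mean normalized count of 10 lost 3 calls under the 6T sgRNA and none under the Luciferase sgRNA. Those lost were nucleic acid sensing, DNA double-strand break repair and spliceosome components. The 8 lists that differed between the sgRNAs became 0 with an estimated correlation and 4 with the order of the conditions reversed in one table. The cause was not tested, other than that a larger correlation widens the test by construction. Over both tables the interferon list had an estimated correlation of 0.00621, below the preset 0.01. Its adjusted p in camera was nevertheless 2.31e-04 with the estimated correlation, against 5.00e-16 with the preset one. Calls lost with an estimated correlation therefore do not measure the correlation between genes alone.

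Pearson's r of −0.25 became −0.10 with a minimum mean of 1, −0.39 with 50, −0.45 with 200, −0.30 without the 1% of genes with the largest change, −0.20 on recovered reads, −0.0272 with GC correction and 0.25 with the order reversed. Spearman's rho of −0.35 became −0.25, −0.44, −0.49, −0.31 on recovered reads, −0.0757 with GC correction and 0.35 with the order reversed. Over both tables, limma's 1 call became 5 with GC correction, 0 with the order reversed in one table and from 0 to 5 without single libraries, named in the report. The interferon list lost its call with that order reversed (adjusted p = 0.881, test direction up, median −0.03). The difference between the sgRNAs had 5 genes with the order reversed and 0 in the other alternatives.

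No paired analysis was possible because the recovered libraries carry no replicate numbers. Count models planned for tables of counts were not run, since the deposited tables hold none, and the authors' own test was not rerun without single libraries. Depth limits genes with few reads, such as CCL5 with 3 reads in condition B under the 6T sgRNA.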

Other observations

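The tests of splits within each table were chosen after the results were seen, and those over both tables were planned before their results were seen.

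Members of fixed lists that the naming rule chose, and that did not pass the authors' deposited test, are given here as values. In the recovered libraries under the Luciferase sgRNA, PPP1R15A, which relieves the block on translation after stress, stood at 1456 ± 368 normalized reads in condition A and 878 ± 88.2 in condition B (SD, n = 3), and HMOX1, the heme oxygenase, at 1267 ± 143 and 972 ± 93.7 (SD, n = 3). SLC3A2, the heavy chain of amino acid transporters, stood at 5328 ± 1197 and 3893 ± 85.8 (SD, n = 3). Under the 6T sgRNA TRIB3, a pseudokinase of the ATF4 response, stood at 549 ± 88.9 and 798 ± 376 normalized reads, and KLF2, a transcription factor of the immediate early list, at 51.7 ± 2.49 and 93.1 ± 50.1 (SD, n = 3), and the libraries of both conditions overlapped for each. In each of these pairs the authors' deposited test gave an adjusted p of 1.

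TM2D3, a membrane protein gene chosen after its values were seen, was at 546 ± 100 and 418 ± 42.5 recovered normalized reads under the 6T sgRNA and at 547 ± 61.4 and 392 ± 17.4 under the Luciferase sgRNA (SD, n = 3). Over both tables its log2 fold change was −0.42, and −0.53 with GC correction, where limma called it (adjusted p = 0.0492).

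Reads that HTSeq left out of genes stood in both tables. As a share of the whole table, 17.6% under the 6T sgRNA and 16.7% under the Luciferase sgRNA had no feature, 1.40% and 1.35% were ambiguous, and 19.7% and 23.6% did not align uniquely. The first principal component of the recovered libraries held 42.5% of the variance, and Luciferase A1 lay farthest along it.

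Over other splits of the 6 libraries of one table, 3 against 3 gives 10 splits, too few for a share under 0.05. In limma the real split of the 6T libraries had 330 genes at an unadjusted p under 0.05, and 6 of the 10 splits had as many, up to 2013. The real Luciferase split had 1345, and 3 of the 10 had as many, up to 2620. Under the 6T sgRNA, splits with several times the real count point to a structure of the libraries other than the condition. Over both tables, of 100 splits drawn from 200, 3 had at least the 1 call of the real one, up to 248. That split points to library structure too, and the comparison was chosen after the same genes had been seen at the top of both tables, so chance is not excluded for the single call although the share was under 0.05. With GC correction only the real split, 1 of 100, had as many as 5 calls, and the highest other had 1. Of these 5 calls 4 are the genes that prompted the comparison, so chance is not excluded there either.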
